A study of Mus musculus with 36 samples.

How the data were processed

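Lung RNA of 29 female C57BL/6 mice was measured on 36 two-colour Agilent mouse arrays. Per the labels, each mouse received a single intratracheal instillation of 0, 18, 54 or 162 µg of tube-shaped titanium dioxide nanoparticles in 40 µl, and the lung was collected at day 1 or day 28. On every array lung RNA was labelled with Cy5 and a universal reference RNA of 11 mouse cell lines with Cy3. The dyes were never swapped, so a dye effect on a probe is shared by all groups and leaves the differences between groups unchanged.

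Groups were taken from the dose and time labels. Arrays with the same sample number and group labels were read as 1 mouse: 7 mice were on 2 arrays each, averaged as 1 replicate. This gives 3 or 4 mice per group, while the labels speak of 5 per group for the RNA. The labels conflict for 1 mouse on 2 arrays, whose titles say day 1 and whose time label says day 28. It was kept in day 28, as replicate 1 at 162 µg, and left out or moved to day 1 as alternatives.

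Per the file headers, spots were quantified with Agilent Feature Extraction 11.0.1.1, and each file gives spot and local background intensities in both dyes. The deposited processed signals are these intensities after background subtraction and dye normalization by the scanner software. The deposited LogRatio column is their log10 ratio of Cy5 over Cy3. The deposited value table holds a log2 ratio of Cy5 over Cy3 with medians of -0.039 to -0.017 per array. How the authors normalized that table is not stated. Its values correlated across probes with the ratios computed here at r = 0.986 to 0.997 per array, and probes are not independent replicates. No spot was saturated.

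All values were computed from the spot intensities with R 4.3.3 and limma 3.58.1, with version 1.17.8 of the data.table package. The median background was removed with normexp and an offset of 50, log2(Cy5/Cy3) was normalized by loess within each array, and spots of one probe were averaged. The plan named mean foreground signals, but the files give medians, which were used. The arrays held 55681 probes. The files give no gene symbol, so probes were named through their RefSeq accession and a table of the GRCm38.p6 assembly, used for names only. This named 28026 probes with 21154 symbols, and the other probes kept the identifier of the file, which gave 36799 gene names. For each name the probe with the highest mean intensity was kept. A gene was tested when it was well above background in Cy5 on every array of at least 3 mice of one group: 23256 genes passed, 15199 of them with a symbol.

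The depth of an array is its signal over background. Per array, 48.6% to 62.2% of the probes were well above background in Cy5, and the median raw Cy5 intensity was 103 to 143.

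One limma model with a mean per group was fitted to all 29 mice, with 21 residual and 2.9 prior degrees of freedom. Each dose was compared with the control group of its day, 162 µg was compared with 54 µg on each day, and the day 28 change was compared with the day 1 change at each dose. The control group of day 28 was also compared with that of day 1. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison. Every test was two-sided. In data simulated for 162 µg against control at day 1, 82% of 50 genes changed 2-fold among the 23256 were recovered. For 18 µg at day 1 it was 76%. In the first, 12 of 167 calls were false. Simulated genes varied independently, without array effects, so these shares may not hold for the mice.

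The comparisons, 27 gene lists and most alternatives were fixed before the data were examined. The lists are named in the results. They hold genes of inflammation, lipid and stress pathways, cell cycle, clock, blood and neighbouring tissue, and immune and lung cell markers. Each list was tested with limma's camera and a preset inter-gene correlation of 0.01 in 9 comparisons, with adjustment over all 243 tests. The test with an estimated correlation and fry were run beside it, and missing values were filled with the group mean for these tests.

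Named genes were chosen by rule among the called genes with every treated mouse on one side of the control mean and a signal above background in each group. These were the 10 largest rises and 5 largest falls for 162 µg against control, 5 and 3 for 54 µg, and 3 and 3 elsewhere. Up to 5 rises (2 at other doses) with the highest lower bound were added where no control array was above background, as were up to 3 called members of each list and 26 genes fixed in advance, of which 1 is not reported here. Cxcl2, one of these, was on the arrays and did not pass the filter. Where a group was not above background on any array, a fold is given as at least that against the background level, or as at least the measured fold where that is lower. Mcm7 and Ccdc167 were named outside the rule, after their values were seen.

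The arrays were scanned on 5 slides in 3 sessions. Slides held 5 to 8 arrays of as many groups, and the slides that carry the repeat arrays were treated as 1 block. Differences within slides or a fit with the slide block are given beside the results. The alternatives changed background correction, normalization, filter, probe choice, handling of repeat arrays and the conflicting label, variance model and groups in the fit. They also left out each mouse in turn and used the deposited table. Chosen after the data had been seen were the skeletal muscle and squamous epithelium lists, the leaving out of arrays whose skeletal muscle level lay more than 2 log2 units above the median array, and the fit with the muscle and squamous scores of each mouse as covariates. So were the phase sets of the clock score, the comparison of repeat arrays and the splits with covariates. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.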

Results

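Lung transcripts of 29 mice were measured on 36 arrays, as log2 ratios of lung RNA over a common reference RNA. At day 1 the groups held 4 control mice (0 µg) and 3, 3 and 4 mice at 18, 54 and 162 µg. At day 28 they held 3 control mice and 4, 4 and 4 mice at these doses. Across genes, which are not independent replicates, mice of one group correlated at a median r of 0.927 (39 pairs, 0.809 to 0.98). On 12 of the 36 arrays the transcripts of skeletal muscle stood apart: the mean log2 Cy5 intensity over a skeletal muscle list was 10.12 to 14.82 on these and at most 8.03 on the other 24. These 12 are called muscle arrays here, and 8 of them also carried transcripts of squamous epithelium, which 0 of the other 24 did. The first principal component, with 42.7% of the variance, was 0.6 to 70.7 on them and -32.7 to 10.3 on the others. At day 1, 4 of 4 control mice had a muscle array, against 1 of 3 at 18 µg (replicate 3), 1 of 3 at 54 µg (replicate 2) and 1 of 4 at 162 µg (replicate 3). At day 28, 0 of 3 control mice had one, against 1 of 4 at 18 µg (replicate 1), 3 of 4 at 54 µg (replicates 1, 2 and 3) and 0 of 4 at 162 µg. Between muscle arrays and the others, doses pooled, the median difference over a list was -0.55 for interferon response and -0.47 for NK cell markers. It was -0.40 for alveolar type I and macrophage, -0.33 for endothelial and -0.31 for alveolar type II markers. It was 0.42 for fatty acid synthesis and 1.23 for blood and neighbouring tissue, which shares Acta1 and Ckm with the skeletal muscle list.

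**Figure D1:**
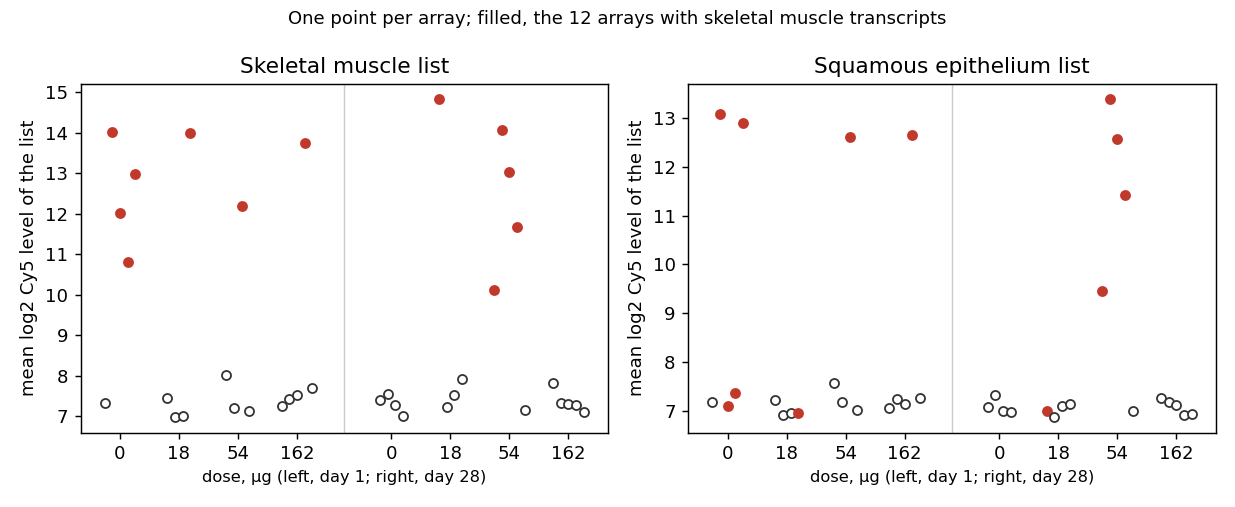
Mean log2 Cy5 intensity over the skeletal muscle list on each of the 36 arrays, by group.

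The comparison of 162 µg with control at day 1 asks which lung transcripts the highest dose changed soon after instillation. Acute phase genes rose furthest. Saa3, a serum amyloid A gene, went from -2.27 ± 0.93 to 4.78 ± 0.77 on the log2 scale (SD, n = 4 and 4), a rise of 133-fold (log2 change 7.06, SE 0.57, adjusted p = 5.13e-08). Saa1 rose 31.6-fold (log2 change 4.98, SE 0.38, adjusted p = 2.21e-08). Lcn2, whose product binds siderophores, rose 5.35-fold (log2 change 2.42, SE 0.29, adjusted p = 3.15e-05). Its mean log2 Cy5 rose more, 17.14 against 13.22. Saa2 was above background on 0 of 5 control arrays and rose at least 17.3-fold (adjusted p = 3.13e-11). Of 18 acute phase genes measured, 9 rose and 0 fell over all genes, and 14 rose adjusted over the list alone (median log2 change 1.75, adjusted p = 4.56e-25, and adjusted p = 0.00472 with an estimated correlation). Timp1, an inhibitor of matrix metalloproteinases, rose 14.4-fold (log2 change 3.85, SE 0.34, adjusted p = 2.27e-07). Slc26a4, the anion exchanger pendrin, rose 11.3-fold (adjusted p = 0.000576). Ly6i and Ly6f, surface antigens of the Ly6 family, rose 9.78-fold and 7.76-fold (adjusted p = 2.08e-05 and 0.000112), and AA467197 rose 7.11-fold (adjusted p = 0.000247). All genes named as changed here had 4 of 4 treated mice on one side of the control mean, for some by the naming rule. Muscle arrays were on 4 of 4 control and 1 of 4 treated mice. The acute phase list kept its call without them and with muscle and squamous scores as covariates (adjusted p = 5.37e-22). Within the 4 slides that held both groups, the change was 5.36 to 8.22 for Saa3 and 0.82 to 2.25 for the median of the acute phase list. With the slide block it was 7.06 for Saa3 (adjusted p = 5.73e-07).

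Chemokine genes rose with them. Of 13 CC chemokines, which attract monocytes and lymphocytes, 7 rose and 0 fell, and 9 rose adjusted over the list alone (median log2 change 1.35, adjusted p = 2.2e-13, and adjusted p = 0.039 with an estimated correlation). Ccl7 rose 5.2-fold (adjusted p = 0.000576), Ccl17 by 2.17 on the log2 scale (adjusted p = 0.000115) and Ccl3 by 1.35 (adjusted p = 0.00102). Of 6 neutrophil chemoattractants 3 rose and 0 fell, and 4 rose adjusted over the list alone (median 0.73, adjusted p = 0.000117, and adjusted p = 0.0989 with an estimated correlation). Cxcl5 rose 5.31-fold (adjusted p = 0.00247), from control values above background on 2 of 5 arrays. Cxcl3 was above background on 0 of 5 control arrays and rose at least 1.87-fold (adjusted p = 0.00142). Of 8 cytokines 3 rose and 0 fell, and 6 rose adjusted over the list alone (median 0.61, adjusted p = 0.000166, and adjusted p = 0.039 with an estimated correlation). Il6, an inducer of the acute phase, did not pass the test (0.51, adjusted p = 0.345). Neutrophil markers did not pass as a list (2 of 16 rose, adjusted p = 0.111). Muscle arrays were those of 4 of 4 control and 1 of 4 treated mice. Without them these 3 lists kept their calls and Ccl17 did not, in a fit that holds 1 control mouse.

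Interferon response genes rose at the same dose and day: 6 of 20 over all genes and 19 adjusted over the list alone (median log2 change 0.76, adjusted p = 1.55e-16), but adjusted p = 0.12 with an estimated correlation. Cxcl10 rose by 2.30 on the log2 scale (adjusted p = 0.00031), Rsad2, an antiviral enzyme, by 1.20 (adjusted p = 0.00397) and Zbp1, a sensor of nucleic acids, by 1.20 (adjusted p = 0.00435). Doses pooled, this list shifted -0.55 on muscle arrays (4 of 4 control, 1 of 4 treated mice), but -0.23 within control replicate 1. Its adjusted p was 4.32e-11 with covariates and 3.76e-15 with the slide block. Cell cycle genes rose (4 of 25, 9 adjusted over the list alone, median 0.41, adjusted p = 7.39e-10, and adjusted p = 0.461 with an estimated correlation). Among these, Mcm5 and Mcm6, parts of the replicative helicase, rose by 0.93 and 1.03 (adjusted p = 0.000247 and 0.000268) and Pbk by 0.87 (adjusted p = 0.00044). Cholesterol synthesis genes rose as a list (1 of 24, 2 adjusted over the list alone, median 0.27, adjusted p = 7.57e-05), with an adjusted p of 0.49 with an estimated correlation. Of its genes Hmgcs1 (0.28) and Sqle (0.34) did not pass singly. Complement genes rose (2 of 13, 4 adjusted over the list alone, median 0.11, adjusted p = 0.0118, and adjusted p = 0.523 with an estimated correlation). Of these C3 was up by 1.46 (adjusted p = 0.00474) and Cfb by 1.12 (adjusted p = 0.00155). Fibroblast and matrix genes, Timp1 among them, rose (3 of 19, 5 adjusted over the list alone, median 0.24, adjusted p = 0.000374, and adjusted p = 0.112 with an estimated correlation). Without the muscle arrays, in that fit with 1 control mouse, the cell cycle, cholesterol synthesis, complement and fibroblast and matrix lists kept their calls. The complement list lost its call without control replicate 1 (adjusted p = 0.103) and without control replicate 4 (adjusted p = 0.0513). All 16 lists called at this dose and day kept their calls with the slide block.

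Markers of airway and resident cells moved both ways. Goblet cell and type 2 epithelial genes rose (2 of 8, 2 adjusted over the list alone, median 0.67, adjusted p = 0.00075, and adjusted p = 0.49 with an estimated correlation). The members called were Slc26a4 and Retnlb, which rose at least 1.48-fold (adjusted p = 0.00953). This list ranged from -0.76 to 2.11 within slides and lost its call without 162 µg replicate 4 (adjusted p = 0.0718). Club and ciliated cell markers fell (1 of 11, median -0.18, adjusted p = 0.00496, and adjusted p = 0.549 with an estimated correlation), with Tppp3 at -0.44 (adjusted p = 0.00723). Alveolar macrophage markers fell as a list (median -0.50, adjusted p = 0.0312, and adjusted p = 0.516 with an estimated correlation), with 2 members down and 1 up. Lipid-laden phagocyte markers (2 of 19 up, median 0.28, adjusted p = 0.0154), lysosome genes (0 of 20 up, median 0.16, adjusted p = 0.0195) and T cell markers (1 of 13 up, median 0.23, adjusted p = 0.0152) rose as lists. Their adjusted p with an estimated correlation were 0.523, 0.516 and 0.609. The list of blood and neighbouring tissue fell (0 of 12, median -1.35, adjusted p = 0.000243, and adjusted p = 0.49 with an estimated correlation). With 4 of 4 control mice and 1 of 4 treated mice on muscle arrays, several of these calls were lost without those arrays. They were those of alveolar macrophage (adjusted p = 0.249), lysosome (0.14), T cell (0.967) and blood genes (0.927). The club and ciliated list turned to a rise that did not pass (0.19). That fit holds 1 control mouse, and clock genes fell in it (0.0269). With the covariates alveolar macrophage (0.0417) and club and ciliated markers (0.0128) kept call and sign, endothelial markers fell (0.0257), and lysosome (0.261), T cell (0.261) and blood genes (0.0512) did not pass. Leaving out 1 mouse also ended calls. Control replicate 2 ended that of alveolar macrophage markers (adjusted p = 0.0689). Control replicate 3 ended those of alveolar macrophage, lipid-laden phagocyte, T cell and club and ciliated markers (0.105, 0.137, 0.0552 and 0.0957), and control replicate 4 the last 3 of these (0.0554, 0.0531 and 0.0658). The same held for 162 µg replicate 3 with alveolar macrophage and club and ciliated markers (0.0889 and 0.22) and 162 µg replicate 4 with alveolar macrophage, lipid-laden phagocyte and lysosome genes (0.0546, 0.0541 and 0.0676). Lists that did not pass (adjusted p = 0.0969 to 0.859) were those of B and plasma cells, eosinophils and mast cells, NK cells, dendritic cells and antigen presentation, alveolar type II, type I and endothelial cells, fatty acid synthesis and the circadian clock. Oxidative stress and metallothionein genes did not pass either (adjusted p = 0.827), and their median of 0.18 and mean of 0.03 had the opposite sign to the test. In this list 2 glutathione transferases fell, Gstm1 by 0.83 (adjusted p = 0.00344) and Gsta3 by 1.04 (adjusted p = 0.00468). Median and mean also differed in sign for alveolar type I markers (-0.09 and 0.08).

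A further set of named genes at 162 µg and day 1 passed with all mice but not without 1 of them. These rises were Il1b (log2 change 1.58, adjusted p = 0.0166), Il33 (1.16, 0.0133), Tnf (0.70, 0.0146), Ccl2 (1.62, 0.0133), Mmp8 (1.01, 0.0159), Clec4d (1.11, 0.0297), Itgax (0.68, 0.0265), Lgals3 (0.68, 0.0271), Icos (0.90, 0.0136), Pdpn (1.12, 0.039), Lox (0.71, 0.015), Col5a1 (0.45, 0.0315) and Tm7sf2 (0.72, 0.0166). Cxcl1 and Mmp12 rose at least 1.68-fold and 1.54-fold (adjusted p = 0.0367 and 0.0428), and Retnlb is given with its list. The falls were Fabp1 (-1.77, adjusted p = 0.0133), Cst8 (-1.27, 0.0229) and Ear2 (-0.98, 0.0151). Without control replicates 1, 2, 3 and 4 in turn, 13, 7, 3 and 12 of these genes lost their call (adjusted p = 0.0522 to 0.137, 0.0502 to 0.118, 0.0787 to 0.0976 and 0.0522 to 0.137). Without 162 µg replicates 1, 2, 3 and 4, 15, 13, 1 and 14 did (adjusted p = 0.0517 to 0.178, 0.0727 to 0.148, 0.0751 and 0.0557 to 0.18). Il1b and Pdpn had the sign of the pooled change in 3 of 4 slides (-0.27 to 2.7 and -0.12 to 1.78). Other falls were Pon1, an esterase (-1.28, adjusted p = 0.0054), Asgr1, a glycoprotein receptor (-1.16, 0.00839), and Hes2, a transcription factor (-1.14, 0.000901), and Adamts4, a matrix protease, rose at least 1.55-fold (adjusted p = 0.00703). With 4 of 4 control and 1 of 4 treated mice on muscle arrays, leaving those arrays out ended the calls of all 5 falls named by size: Fabp1 (adjusted p = 0.152), Pon1 (0.143), Cst8 (0.24), Asgr1 (0.58) and Hes2 (0.134). It also ended those of Cxcl1, Mmp12, Tnf, Ear2, Itgax, Icos, Pdpn, Tppp3 and Ccl2. The covariates ended those of Mmp12 (0.0509) and Lgals3 (0.0574). Genes fixed in advance that did not pass were Spp1 (0.28), Gpnmb (0.56), Hmox1 (0.42), Mt2 (0.76), Scd1 (-0.46), Retnla (0.44), Arg1 (1.62, adjusted p = 0.103), Chil3 (0.51) and Sftpc (-0.58). Arg1 passed without 162 µg replicate 2 (adjusted p = 0.0494) and with the covariates (0.00692). The mean log2 Cy5 of Retnla differed more, 17.01 against 14.06 in control.

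In total 394 of 23256 genes changed for 162 µg against control at day 1, 349 up and 45 down, and 266 of them by at least 1.5-fold. Without 1 mouse the count was 200 (162 µg replicate 1), 223 (162 µg replicate 4), 234 (162 µg replicate 2), 249 (control replicate 1) or 819 (162 µg replicate 3, the treated mouse with a muscle array). Without the muscle arrays, which leaves 1 control mouse whose spread is assumed to be that of the other groups, 471 genes were called, and with the covariates 618. The count was 38 with only the groups compared in the fit, 169 with median centring, 236 with the mouse of conflicting labels in day 1, 834 with all arrays and the mouse as random block, and 3166 with array quality weights. Among 89 other probes of 81 called genes, 5 had the opposite sign and 0 of these by 1.5-fold.

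**Figure D2:**
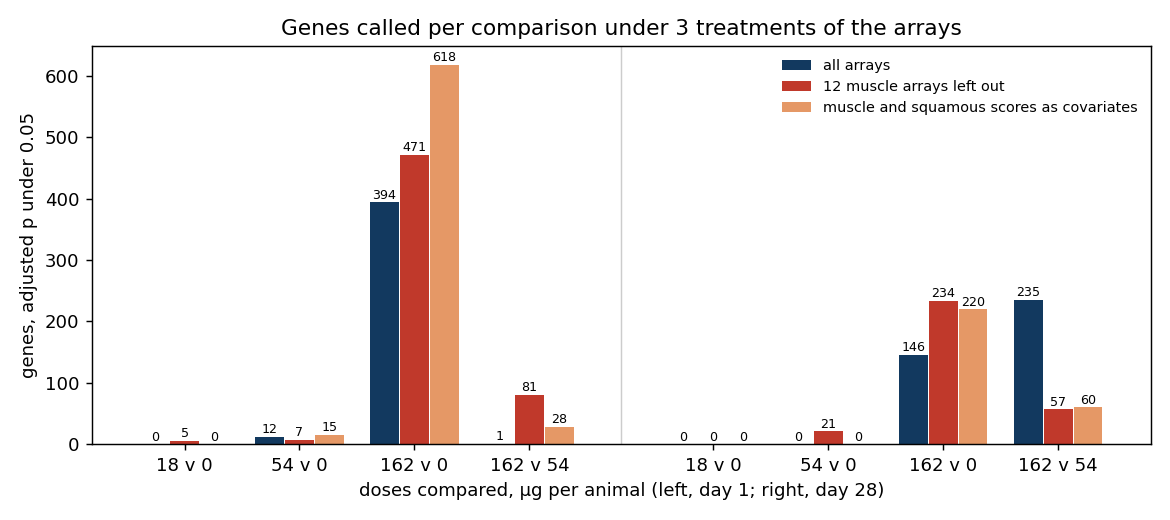
Genes called (adjusted p under 0.05) with all arrays, without muscle arrays and with covariates. With all arrays 18, 54 and 162 µg gave 0, 12 and 394 (day 1) and 0, 0 and 146 (day 28).

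The comparison of 54 µg with control at day 1 asks whether the middle dose changed the same kinds of transcripts. Saa3 rose 24.5-fold, from -2.27 ± 0.93 (SD, n = 4) to 2.34 ± 1.14 (n = 3) on the log2 scale (log2 change 4.62, SE 0.61, adjusted p = 0.00113). Saa2 rose at least 3.72-fold from control arrays that were not above background (adjusted p = 0.000764). Saa1 rose 6.52-fold (adjusted p = 0.00453), Timp1 by 2.25 on the log2 scale (adjusted p = 0.00907), Lcn2 by 2.16 (adjusted p = 0.00381), Ly6i by 2.34 (adjusted p = 0.0204), Ccl17 by 1.71 (adjusted p = 0.029) and Cxcl5 by 2.46 (adjusted p = 0.0472). In these 8 genes 3 of 3 treated mice lay above the control mean, for some by the rule. The sign held in 3 of 3 slides with both groups. Ccl7 (1.98, adjusted p = 0.092) and Ccl2 (1.12, adjusted p = 0.519) did not pass. Acute phase genes rose (5 of 18, 11 adjusted over the list alone, median log2 change 0.98, adjusted p = 4.75e-18, and adjusted p = 0.0128 with an estimated correlation). Neutrophil chemoattractants rose too (1 of 6, 4 adjusted over the list alone, median 0.72, or 0.68 with the dim genes at their bound, adjusted p = 7.79e-06, and adjusted p = 0.0486 with an estimated correlation). CC chemokines rose (1 of 13, 6 adjusted over the list alone, median 0.60, adjusted p = 1.92e-08, and adjusted p = 0.108 with an estimated correlation). Muscle arrays were those of 4 of 4 control mice and 1 of 3 treated mice; the 3 lists kept their calls with the slide block and without these arrays (adjusted p = 3.73e-14, 4.32e-05 and 3.19e-05).

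Lists with no called member at 54 µg and day 1 also passed. Interferon response (median 0.27, adjusted p = 0.000232), cytokine (0.49, 0.00769), lysosome (0.10, 0.00421), T cell (0.27, 0.000378), B and plasma cell (0.26, 0.0455), NK cell (0.28, 0.0295) and cholesterol synthesis genes (0.25, 1.77e-05) rose. With an estimated correlation their adjusted p were 0.185 to 0.677. Club and ciliated cell markers (-0.22, adjusted p = 0.00911) and the list of blood and neighbouring tissue (-1.67, adjusted p = 0.00193) fell, with adjusted p of 0.561 and 0.523 with an estimated correlation. There were muscle arrays for 4 of 4 control and 1 of 3 treated mice. Without those arrays cytokines (adjusted p = 0.072), lysosome (0.133) and B cells (0.807) lost their calls. T cells (0.885), NK cells (0.892), club and ciliated cells (0.261) and blood (0.967) turned in sign. With the covariates lysosome (0.0695), NK cell (0.813) and blood genes (0.183) lost their calls and the other 6 kept them, and lipid-laden phagocyte (0.0314) and goblet genes (0.0255, and 0.00371 without those arrays) rose, as did dendritic cell genes with the slide block (0.0356). Leaving out 1 mouse ended the call of B and plasma cell markers (control replicates 1, 3 and 4, adjusted p = 0.192, 0.38 and 0.2, and 54 µg replicate 2, where it turned in sign, 0.532). It also ended that of NK cell markers (control replicates 2 and 4, 0.052 and 0.087, and 54 µg replicate 3, 0.427). It also ended those of club and ciliated markers (control replicates 3 and 4, 0.144 and 0.137), cytokines (54 µg replicate 2, 0.0824) and blood (54 µg replicate 3, 0.0502).

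The count at 54 µg and day 1 was 12 genes, 12 up and 0 down, of 1768 at an unadjusted p under 0.05. Without 1 mouse it was 2 (54 µg replicate 3), 6 (control replicate 4), 7 (control replicate 1) or 7 (control replicate 2). Without 54 µg replicate 3 the calls of Saa1 (adjusted p = 0.149), Cxcl5 (0.793), Ly6i (0.557), Timp1 (0.283), Lcn2 (0.113) and Ccl17 (0.625) were lost, and those of Saa3 and Saa2 held in each of the fits without 1 mouse. Cxcl5 was also lost without control replicates 1, 2, 3 and 4 (0.195, 0.143, 0.0878 and 0.137) and 54 µg replicate 1 (0.0605), Ly6i without control replicates 1, 2 and 4 (0.0694, 0.0778 and 0.0827) and Timp1 without control replicate 4 (0.0589). Ccl17 was lost without control replicates 2, 3 and 4 (0.143, 0.0578 and 0.15) and 54 µg replicates 1 and 2 (0.0506 and 0.141). With the slide block Cxcl5 (0.0929) and Ccl17 (0.0552) did not pass. Without the muscle arrays Saa3 kept its call, and Saa1 (0.458), Saa2 (0.458), Cxcl5 (0.0791), Ly6i (0.0791), Timp1 (0.294), Lcn2 (0.239) and Ccl17 (0.701) lost theirs; the counts were 7 without these arrays and 15 with the covariates. Other fits gave 0 (only the groups compared), 2 (the mouse of conflicting labels in day 1), 21 (median centring), 25 (one array per mouse) and 93 (array quality weights). The fit without the muscle arrays holds 1 control mouse.

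The comparison of 18 µg with control at day 1 asks whether the lowest dose changed lung transcripts. No single gene passed the test in limma (0 of 23256, with 950 at an unadjusted p under 0.05), and Lcn2 (0.79, adjusted p = 0.912) and Saa3 (-0.45, adjusted p = 0.936) did not pass. Among gene groups, clock genes rose (median 0.57, 7 up and 2 down adjusted over the list alone, adjusted p = 0.000224, and adjusted p = 0.0989 with an estimated correlation). Cell cycle genes fell (median -0.32, adjusted p = 2.42e-07, and adjusted p = 0.516 with an estimated correlation; within slides -0.71 to 0.21), as did cholesterol synthesis genes (-0.16, 0.0144, and adjusted p = 0.604 with an estimated correlation). Eosinophil and mast cell markers (-0.45, adjusted p = 0.042) and blood and neighbouring tissue (-1.47, adjusted p = 2.24e-05) fell, with adjusted p of 0.566 and 0.409 with an estimated correlation. Lysosome (0.13, adjusted p = 0.0312), NK cell (0.32, 0.0035), dendritic cell (0.15, 0.0121), alveolar type II (0.23, 0.00895), alveolar type I (0.34, 0.00468) and endothelial genes (0.27, 0.00315) rose. Estimated correlations gave them adjusted p of 0.418 to 0.566. Muscle arrays were those of 4 of 4 control mice and 1 of 3 treated mice, and without them 0 of these 11 lists kept their call and sign. Eosinophil (adjusted p = 0.927), cholesterol synthesis (0.0396) and cell cycle genes (0.11) turned in sign, and clock (0.975), blood (0.535), lysosome (0.0721), NK cell (0.374), dendritic cell (0.879), alveolar type II (0.625), alveolar type I (0.967) and endothelial genes (0.317) lost their calls. With the covariates clock, cell cycle, dendritic cell and blood genes kept theirs, and neutrophil markers fell (0.0107). Eosinophil markers lost their call with the slide block (adjusted p = 0.0797), which gave a rise of T cell (0.0349) and a fall of club and ciliated (0.0499) and oxidative stress genes (0.025). Leaving out 1 mouse ended the calls of lysosome (control replicate 3, adjusted p = 0.0703, 18 µg replicates 1 and 2, 0.167 and 0.0714) and eosinophil markers (control replicate 2, 0.541, 18 µg replicates 1 and 2, 0.0837 and 0.199). It did so for cholesterol synthesis genes (control replicate 4, 0.619, 18 µg replicates 2 and 3, 0.0644 and 0.084). It ended those of NK cell (18 µg replicate 1, 0.141), dendritic cell (control replicate 3, 0.105) and alveolar type II markers (18 µg replicate 3, 0.0507). Without control replicate 1, 2 genes were called, and without the muscle arrays 5.

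The comparison of 162 µg with 54 µg at day 1 asks which transcripts differed between these doses. Saa2 was 4.67-fold higher at 162 µg (4.17 ± 0.49, n = 4, against 1.94 ± 0.80, n = 3; log2 change 2.22, SE 0.25, adjusted p = 8.74e-05). It was higher by 2.20 with the slide block (adjusted p = 0.00117). This was the only gene called of 1093 at an unadjusted p under 0.05. Saa1 (2.28, adjusted p = 0.0523), Saa3 (2.44, 0.18), Timp1 (1.60, 0.104), Lcn2 (0.26) and Cxcl5 (-0.05) did not pass. Saa1 passed without 54 µg replicate 2 (adjusted p = 0.0433), 54 µg replicate 3 (0.0185) or 162 µg replicate 3 (0.0107), and Timp1 passed without the last of these (0.00512). The count was 3 without 54 µg replicate 3, 24 without 54 µg replicate 2 and 57 without 162 µg replicate 3. These last 2 mice had the muscle arrays of their groups. In all 81 genes were called without muscle arrays, 28 with the covariates, 0 with only the groups compared and 993 with array quality weights.

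**Figure D3:**
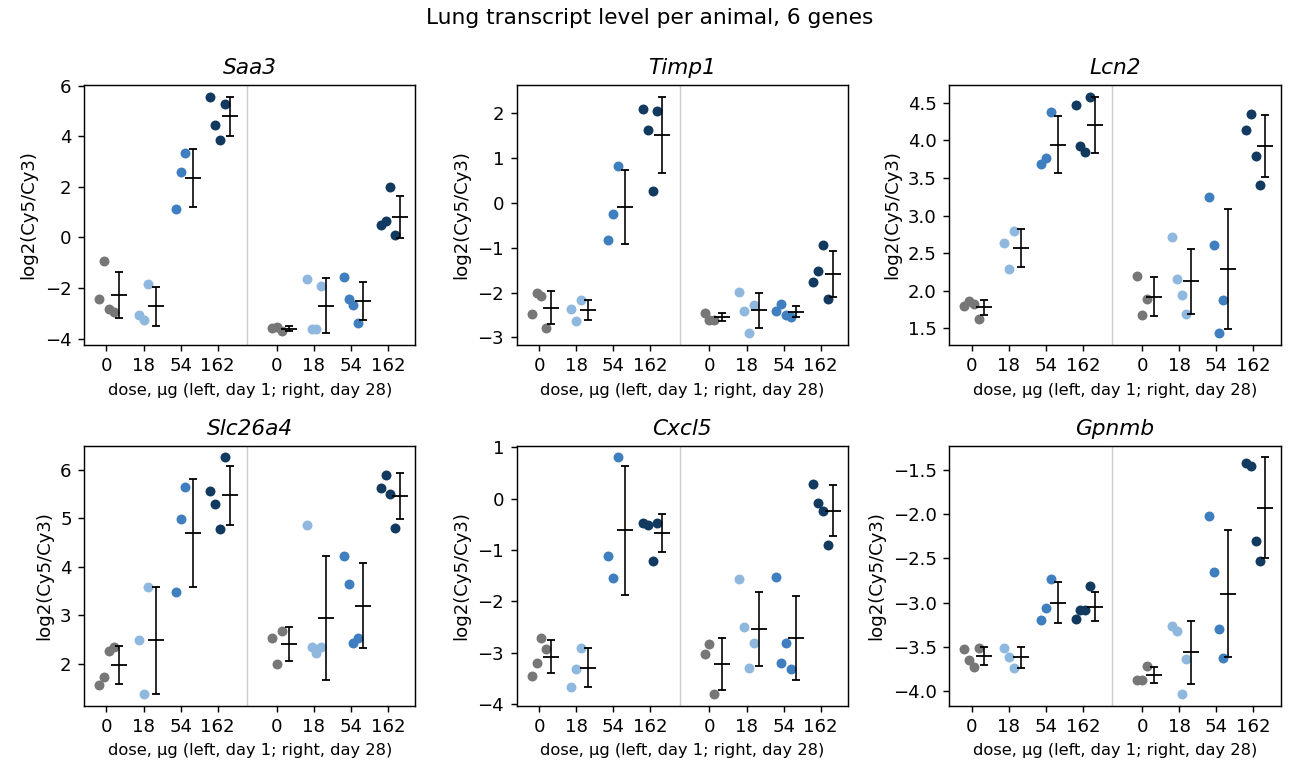
Log2 ratio of Saa3, Timp1, Lcn2, Slc26a4, Cxcl5 and Gpnmb in each mouse by dose and day, with the group mean and SD. At 162 µg the mean of Saa3 was 4.78 at day 1 and 0.81 at day 28, against -2.27 and -3.61 in the controls.

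The comparison of 162 µg with control at day 28 asks which transcripts differed long after the single instillation. Interferon response genes rose furthest as a group: 16 of 20 rose and 0 fell, and 19 rose adjusted over the list alone (median log2 change 1.55, adjusted p = 2.89e-68, and adjusted p = 0.0027 with an estimated correlation). Among them Oas1a, an antiviral oligoadenylate synthetase, rose 5.98-fold (adjusted p = 6.66e-05), Irf7, a transcription factor of the interferon pathway, 4.99-fold (adjusted p = 0.000345), Cxcl10 4.72-fold (adjusted p = 0.00178) and Oasl1 by 1.85 on the log2 scale (adjusted p = 6.66e-05). Ly6i rose 21.9-fold, from 0.53 ± 0.08 (SD, n = 3) to 4.98 ± 0.51 (n = 4; log2 change 4.45, SE 0.41, adjusted p = 2.28e-06), and Ly6f 14.6-fold (log2 change 3.87, SE 0.42, adjusted p = 2.24e-05). Saa3 rose 21.3-fold, from -3.61 ± 0.09 to 0.81 ± 0.83 (log2 change 4.41, SE 0.61, adjusted p = 0.000366), and Lcn2 4.0-fold (adjusted p = 0.00159). Of 18 acute phase genes 4 rose and 0 fell, 5 adjusted over the list alone (median 0.42, adjusted p = 2.05e-12, and adjusted p = 0.039 with an estimated correlation). Cxcl5 rose 7.92-fold (adjusted p = 0.00159), from controls above background on 3 of 4 arrays, and Acod1, which makes itaconate in activated macrophages, 5.23-fold (adjusted p = 0.000222). Muscle arrays were on 0 of these 7 mice. All genes named as changed here had 4 of 4 treated mice on one side of the control mean, for some by the rule. They kept the pooled sign in 3 of 3 slides with both groups. With the slide block Ly6i was 4.37 (adjusted p = 1.54e-05) and Saa3 4.28 (adjusted p = 0.00182).

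Markers of phagocytes and lysosomes rose at 162 µg and day 28. Of 19 markers of lipid-laden phagocytes 4 rose and 0 fell, 8 adjusted over the list alone (median 0.67, adjusted p = 1.52e-18, and adjusted p = 0.00659 with an estimated correlation). Gpnmb, a glycoprotein of lipid-laden macrophages, rose 3.71-fold (log2 change 1.89, SE 0.28, adjusted p = 0.000802) and Trem2, a lipid-sensing receptor, by 1.92 (adjusted p = 0.00272). Lysosome genes rose as a list (0 of 20 over all genes, 7 adjusted over the list alone, median 0.29, adjusted p = 5.52e-12, and adjusted p = 0.0111 with an estimated correlation). Cytokines (0 of 8, 0 adjusted over the list alone, median 0.39, adjusted p = 8.68e-05) and clock genes (2 of 13 up, 6 up and 1 down adjusted over the list alone, median 0.49, adjusted p = 1.23e-06) rose as lists. Each had an adjusted p of 0.039 with an estimated correlation. Dbp, a clock output gene, rose by 1.90 (adjusted p = 0.000735) and Cfb, complement factor B, by 1.17 (adjusted p = 0.00426). CC chemokines rose (3 of 13, 8 adjusted over the list alone, median 0.67, adjusted p = 6.69e-11, and adjusted p = 0.0559 with an estimated correlation). So did neutrophil chemoattractants (1 of 6, 3 adjusted over the list alone, median 0.47, adjusted p = 6.31e-05, and adjusted p = 0.0839 with an estimated correlation). Complement genes rose as well (2 of 13, 4 adjusted over the list alone, median 0.33, adjusted p = 6.06e-08, and adjusted p = 0.0629 with an estimated correlation). NK cell markers fell as a list (0 of 9, median -0.37, adjusted p = 0.000331), with an adjusted p of 0.516 with an estimated correlation. T cell markers (1 of 13, median 0.17, adjusted p = 0.000925), neutrophil markers (1 of 16, 0.14, 0.042) and cell cycle genes (0.14, 0.028) rose as lists, with adjusted p of 0.523, 0.549 and 0.715 with an estimated correlation. Neutrophil markers lost their call without the muscle arrays of the other groups (0.06) and with the covariates (0.0547). Calls of these last 3 lists were lost without control replicate 3 (neutrophil 0.43, cell cycle 0.488), 162 µg replicate 1 (neutrophil 0.386), replicate 2 (T cell 0.0851, cell cycle 0.309), replicate 3 (cell cycle 0.417) or replicate 4 (neutrophil 0.0585), and cell cycle also with the slide block (0.164). The other 12 lists called kept theirs with the slide block. The median and the test differed in sign for club and ciliated markers (0.05) and fatty acid synthesis (0.02), neither of which passed.

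Further named genes at 162 µg and day 28 passed with all mice but not without 1 of them. Slc26a4 rose 8.24-fold (adjusted p = 0.0104), Ifi27l2a, an interferon-induced gene, 7.26-fold (0.021) and Cd200r2 at least 1.63-fold (0.0188). On the log2 scale Itih4 rose by 1.49 (0.0104), Ccl7 by 2.01 (0.0134), Ccl2 by 1.72 (0.0304), Ccl9 by 1.21 (0.0428), Clec4d by 1.41 (0.0156), Ctsk by 1.22 (0.0104), Foxp3, the regulator of regulatory T cells, by 0.58 (0.029), and C4b by 0.78 (0.0322). Rises were seen too in Nr1d1 by 0.91 (0.0105) and Saa1 by 1.79 (0.037), and Hdhd3 fell by 0.74 (0.00631). Without control replicates 1, 2 and 3 in turn 11, 11 and 11 of these lost their call (adjusted p = 0.0516 to 0.217, 0.0752 to 0.229 and 0.0602 to 0.281). Without 162 µg replicates 1, 2, 3 and 4, 7, 11, 5 and 1 did (adjusted p = 0.053 to 0.117, 0.0523 to 0.18, 0.0501 to 0.17 and 0.0547). With the slide block Ccl9 (0.0593), C4b (0.0643) and Saa1 (0.0858) did not pass. Timp1 (0.96, adjusted p = 0.647), Il1b (0.58), Tnf (0.45), Il6 (0.22), Cxcl1 (0.66), Spp1 (0.82, adjusted p = 0.0839), Hmox1 (0.12), Mt2 (0.02), Hmgcs1 (0.20), Sqle (0.16), Scd1 (-0.01), Retnla (0.27), Arg1 (0.13), Chil3 (0.32) and Sftpc (-0.10) did not pass. Mmp12 (adjusted p = 0.0792) passed without 162 µg replicate 3 (0.037), and Spp1 passed without 162 µg replicate 4 (0.0174).

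The count at 162 µg and day 28 was 146 genes, 144 up and 2 down, of 1113 at an unadjusted p under 0.05, and 141 changed by at least 1.5-fold. Of the 349 rises at day 1 and the 144 at day 28, 47 were shared, against 2.16 expected if they were independent. Without 1 mouse the count at day 28 was 65 (control replicate 2), 73 (control replicate 1), 78 (control replicate 3) or 84 (162 µg replicate 2). Without the muscle arrays of the other groups it was 234, and with the covariates 220. It was 88 with the processed signals of the scanner software, 230 with only the groups compared in the fit and 600 with array quality weights.

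At 54 µg and at 18 µg against control at day 28, comparisons that ask whether lower doses left a change, no single gene passed in limma (0 of 23256 each, with 1430 and 1006 at an unadjusted p under 0.05). At 54 µg Saa3 (1.09), Gpnmb (0.92) and Dbp (1.32) each had an adjusted p of 0.749, and at 18 µg Saa3 (0.91) had one of 0.894. Lists of markers fell at 54 µg: NK cells (median -0.44, adjusted p = 0.00121), alveolar type I (-0.37, 0.00128), endothelial (-0.28, 0.00121), alveolar type II (-0.29, 0.0254) and alveolar macrophages (-0.33, 0.0375). Tested with an estimated correlation, they had adjusted p of 0.516 to 0.619. Lipid-laden phagocyte (0.20, adjusted p = 0.027), cholesterol synthesis (0.14, 0.00888), oxidative stress (0.10, 0.0426), cell cycle (0.15, 0.00948), clock (0.17, 0.0185; 2 adjusted over the list alone) and blood genes (0.94, 0.00945) rose. For these the adjusted p with an estimated correlation were 0.468 to 0.677. Muscle arrays were on 3 of 4 mice at 54 µg and 0 of 3 controls. Without them 6 of these 11 lists turned in sign: alveolar macrophages (adjusted p = 0.967), NK cells (0.00739), endothelial (0.249), cholesterol synthesis (0.914), oxidative stress (0.753) and blood (0.033). Alveolar type II (0.333), alveolar type I (0.878), lipid-laden phagocyte (0.666) and clock genes (0.0528) lost their calls there, and club and ciliated markers fell (0.00665). Lipid-laden phagocyte genes lost theirs with the slide block too (0.0648). With the covariates all but lipid-laden phagocyte and clock genes lost theirs (0.354 to 0.896), and acute phase (9.07e-05, against 0.0543 without the covariates) and interferon response genes (1.96e-05, against 0.981) rose. Without these arrays 21 genes were called at 54 µg, from the 1 mouse left in that group. Leaving out control replicate 1 ended the calls of lipid-laden phagocyte (0.0861), cholesterol synthesis (0.0934), oxidative stress (0.0622) and clock genes (0.111). Control replicate 2 ended that of alveolar macrophages (0.104), and control replicate 3 those of alveolar macrophages (0.108), lipid-laden phagocytes (0.0681), alveolar type II (0.0588), oxidative stress (0.107), cell cycle (0.206) and blood (0.281). The 54 µg replicate 1 ended those of lipid-laden phagocytes (0.219) and oxidative stress (0.0581), and replicate 2 those of alveolar macrophages (0.0622), cholesterol synthesis (0.0589), oxidative stress (0.105) and cell cycle (0.192). The 54 µg replicate 3 ended those of alveolar macrophages (0.178), alveolar type II (0.279), oxidative stress (0.0566), clock (0.0543) and blood (0.127), and replicate 4 those of alveolar type II (0.0596), cell cycle (0.0659) and clock (0.0815).

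At 18 µg and day 28, acute phase (median 0.15, adjusted p = 0.00411), eosinophil and mast cell (0.27, 0.0137), goblet (0.57, 0.0118), fatty acid synthesis (0.60, 0.00673) and blood genes (1.57, 0.000852) rose as lists. NK cell (-0.29, 0.00888) and endothelial markers (-0.16, 0.0489) fell. With an estimated correlation the adjusted p were 0.516 to 0.677. Muscle arrays were on 1 of 4 mice at 18 µg and 0 of 3 controls. With the covariates eosinophil (0.101), NK cell (0.086), goblet (0.0695) and endothelial genes (0.317) lost their calls, without these arrays goblet (0.312) and endothelial genes (0.262), and with the slide block endothelial markers (0.0719). These 3 fits each gave a rise of neutrophil markers (0.00683, 0.0044 and 0.042) and a fall of cell cycle genes (0.0416, 0.00342 and 0.00949), and the second a rise of B and plasma cell markers (0.00759). Leaving out control replicate 2 ended the call of endothelial markers (0.158), and control replicate 3 those of NK cell (0.0659), goblet (0.287), endothelial (0.0594) and blood genes (0.095). The 18 µg replicate 1 ended those of goblet (0.148) and endothelial genes (0.484), replicate 2 that of endothelial markers (0.0665), and replicate 4 those of eosinophil (0.231), NK cell (0.123), endothelial (0.111) and fatty acid synthesis genes (0.548).

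The comparison of 162 µg with 54 µg at day 28 asks which transcripts differed between these doses late. Ly6i was 14.5-fold higher at 162 µg (4.98 ± 0.51 against 1.13 ± 1.00, SD, n = 4 and 4; log2 change 3.85, SE 0.38, adjusted p = 8.73e-06), Saa3 10-fold (adjusted p = 0.00256) and Ly6f 8.58-fold (adjusted p = 0.000196). Interferon genes Oas1a (2.31, adjusted p = 0.000196), Oasl1 (1.63, 0.000196) and Rsad2 (1.72, 0.000277) were higher, as were Cxcl5 (2.48, 0.00351), Lcn2 (1.63, 0.0043), C4b (0.83, 0.00743) and Cd200r2, at least 1.65-fold (0.00565). The macrophage and lysosome genes Trem2 (1.46, adjusted p = 0.0126), Cd68 (0.80, 0.0134), Ctsz (0.68, 0.00289), Ctss (1.14, 0.0136), Grn (0.71, 0.0174), Atp6v0d2 (1.26, 0.0202), Itgax (0.67, 0.0393) and Plet1 (1.05, 0.0468) were higher too. So were Itih4 (1.26, adjusted p = 0.0174), Csf2 (1.06, 0.0184), Ccl7 (1.55, 0.0427), Slc26a4 (2.25, 0.046), Cfb (0.98, 0.00865), C1ra (0.68, 0.035) and Saa1 (1.59, 0.0363), while Gpnmb (0.97, 0.0793) and Ccl2 (1.36, 0.0656) did not pass. All had 4 of 4 mice at 162 µg above the mean at 54 µg, for some by the rule. The sign held in 4 of 4 slides. With the slide block Ccl7 (0.057) and Saa1 (0.0523) did not pass, and Ccl2 (0.045) and Spp1 (0.0412) did. The 235 genes called, all up, compare with 2905 at an unadjusted p under 0.05. Muscle arrays were on 3 of 4 mice at 54 µg and 0 of 4 at 162 µg; the count was 57 without these arrays, 60 with the covariates, 52 with only the groups compared in the fit, 151 with the mouse of conflicting labels in day 1 and 3488 with array quality weights. Without them Trem2, Ly6i, Saa3, Oas1a and Lcn2 kept their calls, while Cd68 (0.631), Ctsz (0.76), Ctss (0.272), Grn (1), Atp6v0d2 (0.516), Itgax (1), Plet1 (0.221), Rsad2 (0.19), Cfb (0.141), Csf2 (0.294), Itih4 (0.227), Ccl7 (0.269), Slc26a4 (0.076), Saa1 (0.613) and Cd200r2 (0.28) did not. Trem2 lost its call with the covariates (0.135). Without 1 mouse the count was 101 (162 µg replicate 2), 115 (54 µg replicate 3), 116 (54 µg replicate 2) or 408 (54 µg replicate 4). Without 54 µg replicates 1, 2, 3 and 4, 2, 11, 12 and 4 of the named genes lost their call (adjusted p = 0.053 to 0.0734, 0.0534 to 0.141, 0.0868 to 0.223 and 0.0608 to 0.0752). Without 162 µg replicates 1, 2, 3 and 4, 5, 14, 5 and 4 did (adjusted p = 0.0511 to 0.138, 0.0581 to 0.216, 0.0697 to 0.162 and 0.0509 to 0.135).

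The changes at day 28 and day 1 were compared to ask which responses differed. At 162 µg 6 genes passed, all with a smaller rise at day 28, of 899 at an unadjusted p under 0.05. Without the mouse with conflicting labels, 162 µg replicate 1 of day 28, it was 2 genes, and with that mouse in day 1 it was 0. Saa1 rose by 4.98 at day 1 and 1.79 at day 28 (difference -3.19, SE 0.56, adjusted p = 0.0311). Timp1 rose by 3.85 at day 1 and was 0.96 at day 28 (difference -2.89, SE 0.50, adjusted p = 0.0311), and Mcm2, of the replicative helicase, was 1.19 and 0.01 (difference -1.18, SE 0.19, adjusted p = 0.013). Saa3 (-2.64, adjusted p = 0.748), Gpnmb (1.33, 0.534) and Dbp (1.91, 0.0787) did not pass. Acute phase genes were lower at day 28 in their change (2 of 18, 7 adjusted over the list alone, median -0.83, adjusted p = 7.17e-12) and fibroblast and matrix genes too (1 of 19, median -0.40, adjusted p = 7.79e-06). Clock genes were higher (5 adjusted over the list alone, median 0.30, adjusted p = 7.21e-06). Each of the 3 lists had an adjusted p of 0.039 with an estimated correlation. Fitted with the slide block, Saa1 was -3.27 (adjusted p = 0.049), Timp1 -2.96 (0.0455) and Mcm2 -1.23 (0.00719). Day 1 controls (4 of 4) had muscle arrays and day 28 controls (0 of 3) had none; without these arrays Saa1 (0.143) and Timp1 (0.0597) lost their calls, and 15 genes were called.

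Single mice decided several of these differences between days at 162 µg. Without 1 mouse the calls of Saa1 and Timp1 were lost in 12 of 15 fits. From day 1 these were control replicates 1, 3 and 4 (Saa1 0.0738, 0.0785 and 0.0823) and 162 µg replicates 1, 2 and 4 (0.117, 0.0703 and 0.0767). From day 28 they were control replicates 1, 2 and 3 (0.138, 0.0979 and 0.0697) and 162 µg replicates 1, 2 and 4 (0.106, 0.0656 and 0.0791). Timp1 had adjusted p of 0.0513 to 0.138 in these fits. Mcm2 was lost without 162 µg replicates 1, 2 and 4 of day 1 (0.0528, 0.0503 and 0.0513), control replicates 1 and 2 of day 28 (0.0728 and 0.0921) and 162 µg replicate 1 of day 28 (0.0518). The count was 28 without 162 µg replicate 3 and 10 without control replicate 2 of day 1. It was 1 without 162 µg replicate 1, 2 or 4 of day 1 or control replicate 1 or 2 of day 28, and 2 to 4 without control replicate 1, 3 or 4 of day 1, control replicate 3 or 162 µg replicate 1, 2 or 4 of day 28.

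At 54 µg and 18 µg no gene passed in limma for the difference between days (0 each, with 2371 and 1553 at an unadjusted p under 0.05). At 54 µg Saa3 (-3.53), Saa1 (-2.50) and Lcn2 (-1.79) each had an adjusted p of 0.489, and at 18 µg Saa3 (1.36) had one of 0.692. The acute phase list was lower in its change at 54 µg (median -0.68, adjusted p = 2.32e-06, and adjusted p = 0.191 with an estimated correlation). Muscle arrays were on 4 of 4 day 1 controls and 3 of 4 mice at 54 µg and day 28, and 18 genes were called at 54 µg and 3 at 18 µg without them. Without 54 µg replicate 1 of day 1, 1 gene passed at 54 µg.

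The control groups of day 28 and day 1 were compared to see what differs without particles. No gene passed in limma (0 of 23256, with 1162 at an unadjusted p under 0.05), and Dbp had the lowest adjusted p (-1.72, adjusted p = 0.0538). Saa3 (-1.33, adjusted p = 0.777), Lcn2 (0.14) and Gpnmb (-0.22) did not pass. Without control replicate 4 of day 1, 1 gene passed, and 12 passed without the muscle arrays, which 4 of 4 control mice of day 1 and 0 of 3 of day 28 had. A clock score was the median of 8 genes peaking with Dbp minus that of 3 peaking with Arntl. It was 0.76 ± 0.57 (SD, n = 4) in controls at day 1 and -0.34 ± 0.12 (n = 3) at day 28. The difference was -1.10 (exact permutation test, two-sided, p = 0.0571, 0.103 after adjustment over 9 comparisons). At day 28 the score was -0.30 ± 0.29 at 18 µg, 0.42 ± 0.13 at 54 µg and 0.88 ± 0.31 at 162 µg (n = 4 each), or 0.04, 0.76 and 1.22 above control (exact permutation tests, p = 0.857, 0.0286 and 0.0286, the smallest possible, and 0.964, 0.0858 and 0.0858 after adjustment). The 162 µg group lay 0.46 above 54 µg (exact permutation test, p = 0.0286, 0.0858 after adjustment). At day 1 the score was 1.88 ± 0.13 at 18 µg, 1.00 ± 0.10 at 54 µg (n = 3 each) and 0.79 ± 0.27 at 162 µg (n = 4), or 1.12, 0.25 and 0.03 above control (exact permutation tests, p = 0.0571, 0.657 and 0.971). The 162 µg group lay 0.21 below 54 µg (exact permutation test, p = 0.286).

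**Figure D4:**
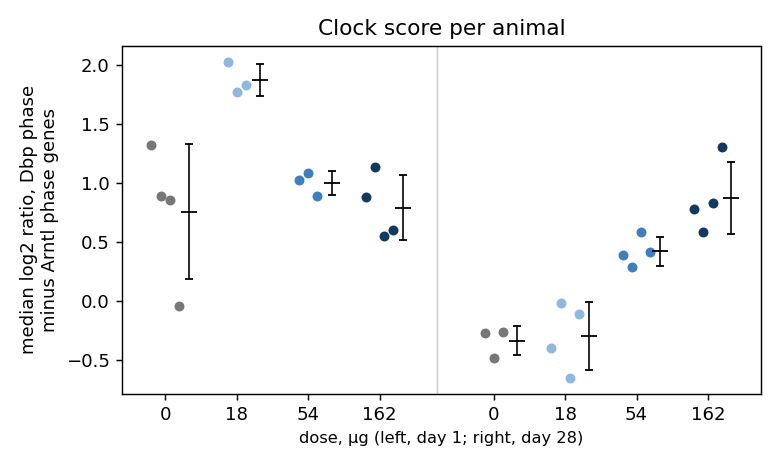
Clock score of each mouse by group, in log2 units, with the group mean and SD.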

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

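Some tests were chosen only after the result was seen. These were a mouse response for the muscle arrays and muscle tissue for the larger count against 54 µg. For the clock genes they were time of day, particles and muscle tissue.

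Skeletal muscle transcripts stood out on 12 of the 36 arrays, with a median shift of 5.11 in Cy5 over the 22 genes of the list and 3.93 over the squamous epithelium list. In a second skeletal muscle list 17 of 18 genes (94.4%) were over 2-fold higher on these arrays, against 2.04% of all gene names, which is consistent with RNA of neighbouring tissue in the lung piece. A fault of the array or the hybridisation is argued against by the reference channel, where the shift was 0.26, or 0.052 of that in Cy5. A response of the mouse to the particles is argued against by the day 1 controls, which received 0 µg and all had muscle arrays. The 2 arrays of control replicate 1 lay at 7.32 and 14.02, 6.7 apart, which adds to this only if they are 1 mouse. Neighbouring tissue may thus add where groups differ in muscle arrays.

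At day 28 more genes were called for 162 µg against 54 µg (235) than for 162 µg against control (146). Without 1 mouse the first count was 101 (162 µg replicate 2), 115 and 116 (54 µg replicates 3 and 2) or 408 (54 µg replicate 4), and the second 65, 73 and 78 (control replicates 2, 1 and 3) or 84 (162 µg replicate 2). With the muscle and squamous scores as covariates the counts were 60 and 220, so muscle tissue on arrays of the 54 µg group, which 3 of 4 mice had, is a candidate explanation for the larger count. A lower level at 54 µg than in control is argued against: over the genes called, the median change of 54 µg against control was 0.13 with the covariates (IQR 0.23) and -0.08 without, while that of 162 µg against control was 0.84 in both.

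Circadian clock genes differed between groups, the controls of the 2 days included. Between these controls the Dbp-phase genes minus the Arntl-phase genes gave -0.7, which a difference in time of day at tissue collection could produce. A response to the particles could produce the clock scores at day 28, graded from 54 to 162 µg (0.87 at 162 µg by the same measure), but the control difference, without particles, was 0.8 of it, and at day 1 the score was highest at 18 µg. Muscle tissue on the arrays is argued against for the control groups, 4 of 4 and 0 of 3 of which had a muscle array, since with the covariates their difference was -0.71, a share of 1.01, but it is left open at 18 µg and day 1, where the clock list kept its call with the covariates (0.00105) and lost it without the muscle arrays (0.975, with 1 control mouse). Time of day and a response to the particles cannot be told apart, since the labels give no time of day and both could move the same genes.

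Single mice far from the others of their group were found in 32 of 570 tests (5.6%) on groups of 4, by the gap to the nearest mouse as a share of the range (given for each), where chance gives about 1 in 20 (28.5). Of the 32, 9 belong to 162 µg replicate 3 of day 1, which had the muscle array of its group. They are low values for Cxcl5 (0.96), Mcm2 (0.984), Mcm5 (0.846), Ly6i (0.911), Ctsz (0.85), Lgals3 (0.848) and Sqle (0.845) and high ones for the skeletal muscle score (0.914) and the squamous epithelium score (0.937). At the same dose and day replicate 4 was high for Hmox1 (0.842) and the goblet list (0.855) and low for the cholesterol synthesis list (0.88). Among day 1 controls replicate 2 was low for Lgals3 (0.875) and high for Mcm2 (0.95) and Mcm6 (0.832), and replicate 4 was low for Dbp (0.933).

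At 18 µg and day 28, replicate 1 was high for Slc26a4 (0.953), the goblet list (0.891) and the skeletal muscle score (0.882). Replicate 3 was low for Nr1d1 (0.863) and high for cytokines (0.865). Replicate 4 was high for Col5a1 (0.833) and B and plasma cell markers (0.908) and low for Saa2 (0.855) and Zbp1 (0.886). At 54 µg and day 28, replicate 1 was high for Saa2 (0.959). Replicate 3 was low for Ear2 (0.937) and high for Scd1 (0.884). Replicate 4 was low for Mmp12 (0.83) and high for Pon1 (0.971). At 162 µg and day 28, replicate 3 was high for Col5a1 (0.91) and replicate 4 low for Acod1 (0.902).

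The change at 162 µg differed between the days in 6 genes, each with a smaller rise at day 28. Their adjusted p in limma were 2.31e-06 for Saa2, 0.0311 for Saa1, 0.0311 for Timp1, 0.013 for Mcm2, 0.013 for Ccdc167 and 0.034 for Mcm7. The count was 28 without 162 µg replicate 3 of day 1, 10 without control replicate 2 of day 1 and 1 without control replicate 1 of day 28. Saa1 and Timp1 lost their calls in 12 fits without 1 mouse, with up to 0.138 without day 28 control replicate 1.

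Gene lists whose change differed between the days number 37 of 81. At 162 µg the change was lower at day 28 for acute phase (adjusted p = 7.17e-12), CC chemokine (0.0112), NK cell (2.24e-05), goblet (0.0413), fibroblast and matrix (7.79e-06), cholesterol synthesis (0.0118) and cell cycle genes (7.54e-06). It was higher for interferon response (2.98e-11), alveolar macrophage (0.000699), lipid-laden phagocyte (1.49e-05), lysosome (0.00777), club and ciliated cell (0.0124), clock (7.21e-06) and blood genes (0.0121). At 54 µg it was lower for acute phase (2.32e-06), neutrophil chemoattractant (0.0035), CC chemokine (0.00616), interferon response (0.0156), lysosome (0.0413), T cell (0.0132), NK cell (0.000581), dendritic cell (0.0396), alveolar type II (0.0207), alveolar type I (0.00271) and endothelial genes (0.0174). It was higher there for cell cycle (0.00967) and blood genes (0.000255). At 18 µg it was lower for NK cell (0.000374), alveolar type II (0.0119), alveolar type I (0.0138), endothelial (0.00173) and clock genes (0.0271). It was higher for lipid-laden phagocyte (0.0421), eosinophil and mast cell (0.00464), fatty acid synthesis (0.00777), cell cycle (0.0492) and blood genes (1.61e-06). With an estimated correlation 3 of the 37 pass, those of acute phase, fibroblast and matrix and clock genes at 162 µg (adjusted p = 0.039 each). Without the muscle arrays 20 of the 37 lose their call or turn in sign, 7 of 10 at 18 µg, 9 of 13 at 54 µg and 4 of 14 at 162 µg, with up to 0.938 for alveolar type I genes at 18 µg. With the covariates it is 9 of 10, 10 of 13 and 1 of 14, with up to 0.896 for alveolar type I genes at 54 µg. These fits also call 6 and 4 lists not among the 37. Without 1 mouse 19 of the 37 lose their call in at least 1 fit. At 18 µg the highest are cell cycle (0.517) and clock genes (0.1) without 18 µg replicate 3 of day 1, lipid-laden phagocyte (0.208, day 1 control replicate 2), fatty acid synthesis (0.123, day 28 replicate 4) and alveolar type I genes (0.0657, day 28 replicate 1). At 54 µg they are alveolar type II (0.286), endothelial (0.27), cell cycle (0.159) and interferon response genes (0.0689) without replicate 3 of day 1, dendritic cell (0.154), T cell (0.138) and CC chemokine genes (0.0558) without replicate 2 of day 1, and lysosome genes (0.131, day 28 replicate 2). At 162 µg they are goblet (0.646) and CC chemokine genes (0.116) without replicate 4 of day 1, club and ciliated (0.282) and lysosome genes (0.079) without replicate 3 of day 1, blood genes (0.249, day 28 control replicate 3) and cholesterol synthesis genes (0.153, day 28 replicate 4). With the slide block 5 lose it: lipid-laden phagocyte (0.13), cell cycle (0.172) and clock genes (0.115) at 18 µg, lysosome genes (0.061) at 54 µg and goblet genes (0.0677) at 162 µg. That fit calls 4 others: neutrophil markers (0.0132) and goblet genes (0.0455) at 18 µg, oxidative stress genes (0.0175) at 54 µg and alveolar type II markers (0.0413) at 162 µg.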

How the results depend on the processing

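The leaving out of muscle arrays and the fit with the muscle and squamous scores as covariates were chosen only after the data had been seen. No paired analysis was possible, since replicate numbers count different mice and no mouse is in more than 1 group. The fit with the slide block matched groups by slide. Among 383 results for named genes, 0 turned in sign under any alternative where either fit called the gene. The calls of Saa3, Saa1, Saa2, Timp1, Slc26a4, Ly6i, Ly6f, AA467197, Lcn2, Cxcl5, Ccl7, Rsad2 and Pbk at 162 µg and day 1 held under every alternative that tested them and without any 1 mouse. So did those of Ly6i, Saa3, Ly6f, Cxcl5, Oas1a, Acod1, Irf7, Cxcl10, Oasl1, Lcn2, Gpnmb, Trem2, Cfb and Dbp at 162 µg and day 28. Named genes lost 242 calls and gained 15 over 3353 results from fits without 1 mouse, lost 40 and gained 2 without the muscle arrays and lost 65 with only the groups compared in the fit. Of 243 list results 93 lost their call with an estimated correlation and 84 with fry. Changes from a group not above background are given as bounds.

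Without 1 mouse the counts were 0 to 2 for 18 µg, 2 to 10 for 54 µg and 200 to 819 for 162 µg at day 1, and 1 to 57 for 162 µg against 54 µg. The 2 genes at 18 µg were called without control replicate 1. At day 28 they were 0 to 0 for 18 µg and for 54 µg, 65 to 128 for 162 µg and 101 to 408 for 162 µg against 54 µg. They were 0 to 0, 0 to 1 and 1 to 28 for the differences between days at 18, 54 and 162 µg and 0 to 1 for the controls. The animals behind the extremes at 162 µg are control replicate 2 (65), 162 µg replicate 2 (101) and 54 µg replicate 4 (408) at day 28 and 162 µg replicates 1 (200) and 3 (819) at day 1.

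With the processed signals of the scanner software the count was 0 for 162 µg against 54 µg at day 1, 1 for 54 µg and 88 for 162 µg at day 28, and 0 for the difference at 162 µg. Median centring gave 21 for 54 µg and 169 for 162 µg at day 1, 2 for 162 µg against 54 µg, 1 for the difference at 54 µg and 3 for that at 162 µg, and moved the median of all genes by -0.316 to 0.233. The Cy5 channel alone gave 13 for 162 µg against 54 µg at day 1. Testing only genes above background on all arrays, which are fewer, gave 0 for this comparison and 1 for the controls. Testing every probe gave 2. With one array per mouse the count was 2 for 18 µg and 25 for 54 µg at day 1 and 1 for the difference at 54 µg. With all arrays and the mouse as random block, whose correlation was -0.034, it was 834 for 162 µg at day 1, 109 for 162 µg against 54 µg and 38 for the difference at 162 µg. Trend and robust gave 1 for the controls. Array quality weights of 0.233 to 4.736 gave 3, 93 and 3166 for 18, 54 and 162 µg and 993 for 162 µg against 54 µg at day 1. They gave 1614, 600 and 3488 for 54 µg, 162 µg and 162 µg against 54 µg at day 28, 2819 and 465 for the differences at 54 and 162 µg and 2 for the controls. With only the groups compared in the fit, and so fewer mice to estimate the spread, the counts were 0 for 54 µg, 38 for 162 µg and 0 for 162 µg against 54 µg at day 1. They were 230 and 52 for the last pair of comparisons at day 28 and 2 for the difference at 162 µg. Leaving out the mouse with conflicting labels gave 2 for the difference at 162 µg. Placing it in day 1 gave 2, 236 and 0 for 54 µg, 162 µg and 162 µg against 54 µg at day 1, 151 for the last at day 28 and 0 for the difference at 162 µg. Except where stated, the cause of these changes was not tested.

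Without the muscle arrays, and so with fewer mice, the counts were 5, 7 and 81 for 18 µg, 54 µg and 162 µg against 54 µg at day 1. They were 21, 234 and 57 for 54 µg, 162 µg and 162 µg against 54 µg at day 28, 3, 18 and 15 for the differences at 18, 54 and 162 µg and 12 for the controls. This leaves 1 control mouse at day 1 and 1 mouse at 54 µg and day 28, assumed to vary like the other groups. With the covariates the counts were 618 for 162 µg and 28 for 162 µg against 54 µg at day 1, and 220 and 60 for the same at day 28. The number of gene list tests that passed was 107 of 243 as reported, 67 without the muscle arrays, 14 with an estimated correlation and 23 with fry.

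Lists called in at least 1 of the 2 fits that turned in sign without the muscle arrays had these adjusted p. At day 1 they were eosinophil (0.927), cholesterol synthesis (0.0396) and cell cycle genes (0.11) at 18 µg, T cell (0.885), NK cell (0.892), club and ciliated (0.261) and blood genes (0.967) at 54 µg, and club and ciliated genes (0.19) at 162 µg. At 54 µg and day 28 they were alveolar macrophage (0.967), NK cell (0.00739), endothelial (0.249), cholesterol synthesis (0.914), oxidative stress (0.753) and blood genes (0.033). For the difference between days they were cell cycle (0.00333) and clock genes (0.705) at 18 µg, T cell (0.179), NK cell (0.0816), dendritic cell (0.883), club and ciliated (0.00729), endothelial (0.667) and blood genes (0.203) at 54 µg, and club and ciliated (0.136) and blood genes (0.666) at 162 µg. With the covariates interferon response (1.96e-05), cell cycle (0.493) and blood genes (0.445) turned at 54 µg and day 28 by the same rule, and interferon response (0.668) and endothelial genes (0.433) in the difference at 54 µg. Without 54 µg replicate 2, B and plasma cell markers, 54 µg against control at day 1, turned (0.532), and the lowest adjusted p of this list was 1.5e-06, without control replicate 2. The cause of these turns was not tested further.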

Other observations

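The comparison of repeat arrays and the splits with covariates were chosen only after the values were seen.

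The 7 mice measured on 2 arrays each gave 7 repeat pairs. The 2 pairs with a muscle array correlated across genes at r = 0.818 (day 1 control replicate 1) and 0.882 (day 28, 54 µg replicate 1), and the 5 others at 0.96 to 0.968 with a median of 0.967. For 26 pairs of different mice of one group without muscle arrays the median was 0.964 (0.927 to 0.98), and between groups 0.956. Of the 14 arrays 0 lay closest to their own repeat. These values thus do not show that the arrays of a pair are 1 mouse, so the count of 29 mice rests on the labels. The clock score differed within a pair by a median of 0.32 and at most by 1.65 (day 1 control replicate 1, 0.34 on the muscle array and 1.99 on the other; the second highest was 0.65), against 0.29 between mice of one group and 0.83 between groups.

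Other splits of the same mice were fitted to see what chance gives. For 162 µg against control at day 28, 1 of 35 splits, the real one, gave 146 genes and the highest other gave 16. This is the smallest share that 35 splits can give. It is not adjusted over the comparisons, so chance is not excluded by it alone. The same holds for 162 µg against 54 µg at day 28 (1 of 35, 235 and at most 4 in another split). For 162 µg against control at day 1, 2 of 35 splits gave as many as the real 394, so chance cannot be excluded. The other gave 679 and set control replicate 3 with 162 µg replicates 1, 2 and 4, which follows the muscle arrays in 7 of 8 mice. With the covariates 1 of 35 splits, the real one, gave 618 and the highest other 104. The same fit gave 15 for 54 µg at day 1 with 109 in another split (3 of 35 as large), 28 for 162 µg against 54 µg at day 1 with 51 (2 of 35), and 0 for 18 µg at day 1 with 142 (35 of 35). At day 28 it gave 220 for 162 µg with 42 and 60 for 162 µg against 54 µg with 1 (1 of 35 each). The real count itself was 200 without 162 µg replicate 1 and 819 without replicate 3. For 54 µg at day 1, 2 of 35 splits gave as many as 12, with 16 in the other, and chance cannot be excluded. For 162 µg against 54 µg at day 1, 5 of 35 gave at least 1 gene. The highest, 64, set the 54 µg mice with 162 µg replicate 3, and points to a structure of the samples. For the difference at 162 µg, 3 of 100 drawn splits gave at least 6 genes, a share that is likewise not adjusted over the comparisons. The highest other gave 127 and points to a structure too. The real count was 1 without any 1 of 162 µg replicates 1, 2 and 4 of day 1 and control replicates 1 and 2 of day 28. Where 0 genes were called, every split gave as many: 35 of 35 for 18 µg at day 1 (highest 0), for 18 µg and 54 µg at day 28 (0 and 0) and for the controls (2), and 100 of 100 for the differences at 18 and 54 µg (highest 4 and 263). The last points to a structure.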
